A study of Homo sapiens with 4 samples.

How the data were processed

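Total RNA from human umbilical vein endothelial cells (HUVEC, a primary endothelial cell type) and from mesenchymal stem cells (MSC, which the sample titles write as MCS) was sequenced after growth on conventional tissue culture plastic or on a patterned substrate carrying titanium diboride (TiB2), a conductive ceramic. Per the labels' protocols, cells of passages 1 to 9 were seeded at 600 cells per square millimetre, in medium with 20% fetal bovine serum for HUVEC and 10% for MSC. Per the labels' protocols, libraries were made from 100 ng of RNA with a stranded total RNA kit, which keeps the strand of the transcript. There were 4 libraries, 1 for each cell type and surface, so no group had replicates and no difference between surfaces has a replicate check.

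The authors deposited 1 table per cell type, with whole-number read counts per gene, RPKM, TPM and a column named CPM for each library, per the file headers. The submitters' processing notes name the genome build hg38 and the program DESeq2. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. The deposited TPM columns summed to the same total in each library. In the column named CPM in the file headers, every value was the count divided by 1 number per library, and the columns summed to 1201444, 832332, 869671 and 956337 for HUVEC plastic, HUVEC TiB2, MSC plastic and MSC TiB2. In HUVEC those numbers equalled the library sizes after edgeR's TMM scaling, and in MSC they did not. The deposited RPKM values implied denominators of 1410253, 569167, 2133598 and 1549031 reads in the same order, of which the deposited counts made up 5.73%, 8.12%, 1.52% and 2.31%. The counts were used for every result below, and the RPKM, TPM and CPM columns only for these checks.

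Each table held 21515 genes, and 27 gene symbols that had been turned into dates were restored from their Ensembl identifiers. The counts summed to 80833 in HUVEC plastic, 46214 in HUVEC TiB2, 32424 in MSC plastic and 35801 in MSC TiB2. The smallest share that 3 reads represent was between 0.00371% and 0.00925% of a library's counts. Intervals are at the 95% level: exact Clopper-Pearson for shares of reads, exact conditional binomial for ratios of 2 counts, and approximate Wilson intervals for shares of genes. Those of read shares and ratios cover counting error only, because reads made by PCR without molecular identifiers are not independent molecules. The interval of the correlation between cell types is an approximation over genes. Where a library had 0 reads, a bound on the fold difference was computed against a floor of 3 reads per library, with the other count taken without its counting error.

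For each cell type, the log2 ratio of TiB2 over plastic was taken from TMM-scaled counts with a prior count of 2 (edgeR 4.0.16 in R 4.3.3), for genes with at least 50 reads over both libraries, and a gene was called at a log2 ratio of 1 or more in size. No test was run across genes. Because the TMM scale moved the median gene of HUVEC, ratios are also given as ratios of shares of nuclear counts, which are the counts outside the mitochondrial genes. On the TMM scale nuclear counts as a whole had a log2 ratio of -1.17 in HUVEC and 0.0018 in MSC, so each HUVEC ratio of nuclear shares is higher than its TMM ratio by that amount on the log2 scale, and the MSC ratios are nearly equal. On counts simulated from the real libraries with 200 genes changed 4-fold, run on 21515 genes, 83 of the 85 changed genes over the floor were called in HUVEC and 1 of 163 unchanged genes. In the MSC simulation these were 79 of 79 changed genes and 0 of 75 unchanged genes. Apart from the changed genes, both simulated libraries were drawn as independent reads from the pooled profile of the real ones. They held neither the differing mitochondrial shares nor the grouped counts of HUVEC TiB2 described below. The rates therefore check the calculation and do not describe the error of the real comparisons.

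Before the data were examined, the groups, the design, the alternatives, 44 gene lists with 723 entries and the rule for named genes were fixed. Of the entries, 686 were found in the tables, and 41 lists had members there. For each list with 3 or more members with reads, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. The pooled reads of a list as a share of nuclear counts were chosen as a second summary after the data were seen, because the planned percentiles set few lists apart; the division of HUVEC TiB2 reads by 6 was chosen then too. The rule named, per comparison, the 8 highest and 8 lowest called genes with a mean of at least 50 normalized reads, up to 4 members of each list at that floor, and PECAM1, CDH5 and VWF in HUVEC or THY1, NT5E, ENG and COL1A1 in MSC. For the comparison of responses it named up to 5 genes called in both cell types per sign pattern. Other genes named below were chosen after their values were seen. They are the member with most reads of a list, genes with most reads in a library, and genes opposite a list member. Y-linked genes and XIST were left out of all gene results, and some genes and a list that the rules take in are not reported here.

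Positions are those of the deposited tables (hg38, counted from 1). Exons on the other strand were taken from GENCODE release 29, which holds 21458 of the identifiers, 14219 of them with the same start, end and strand. A gene was said to lie opposite another when their exons shared at least 100 bases on different strands. Reads of near-identical copies (ribosomal protein and actin pseudogenes, PRPS1L1 and PRPS1), of overlapping mitochondrial genes (MT-ATP8 with MT-ATP6, MT-ND4L with MT-ND4) and of genes opposite each other, VIM with VIM-AS1 and TTN with TTN-AS1 among them, may have been split by the counting in ways that are not given here, so their levels are uncertain. To compare the number of genes detected, reads were drawn without replacement from a library 100 times. Alternatives were DESeq2 1.42.0 size factors, total counts, other floors, prior counts and thresholds, centring on the median gene, and other summaries of the lists. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.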

Results

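Gene expression was measured by total RNA sequencing in HUVEC and MSC on tissue culture plastic and on patterned TiB2 substrates, with 1 library per cell type and surface. The libraries held 80833 (HUVEC plastic), 46214 (HUVEC TiB2), 32424 (MSC plastic) and 35801 (MSC TiB2) counted reads. Reads were found on 8294, 2441, 5811 and 6147 genes in the same order, and 170, 62, 67 and 61 genes had 50 or more. At this depth most genes had only a few reads, so the values below concern the genes with most reads and pooled groups of genes. They are reads counted on each gene and may not measure its own transcripts. Most nuclear genes with 50 or more reads lay opposite a protein-coding exon, and counting on the other strand is weighed at the end. All differences are between single libraries, without a replicate check.

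The libraries carried the markers of their labels. Endothelial markers took 0.280% of nuclear counts in HUVEC plastic (95% interval 0.240 to 0.325, Clopper-Pearson) and 0.287% in HUVEC TiB2 (0.222 to 0.366), against 0.00346% in MSC plastic (1 read) and 0.0172% in MSC TiB2 (5 reads). Mesenchymal stromal markers took 0.723% in MSC plastic (0.628 to 0.827) and 0.650% in MSC TiB2 (0.561 to 0.749), against 0.0566% and 0.0442% in HUVEC plastic and TiB2. PECAM1, an endothelial junction protein, had 45 reads in HUVEC plastic and 22 in HUVEC TiB2, and CDH5, the endothelial cadherin, had 31 and 12. As ratios of nuclear shares, TiB2 over plastic, these were 1.34 (0.763 to 2.27) and 1.06 (0.494 to 2.12), but on the TMM scale 0.592 (0.339 to 1.01) and 0.469 (0.219 to 0.939), and the pooled endothelial markers had 0.455 (0.337 to 0.609) there. VWF, the von Willebrand factor, had 23 and 1 reads, a ratio of 0.119 (0.00288 to 0.731). In MSC, the surface markers THY1, NT5E and ENG had 7, 6 and 1 reads on plastic and 4, 7 and 5 on TiB2, too few to compare. Leukocyte markers had 8, 0, 3 and 0 reads over the libraries in the order above, epithelial markers 6, 0, 4 and 1, and lymphatic endothelial markers 7, 0, 0 and 0. Smooth muscle and pericyte contractile genes had 68, 38, 79 and 58 reads, or 0.110%, 0.168%, 0.273% and 0.199% of nuclear counts. In HUVEC their ratio was 1.53 (0.998 to 2.30), but 0.677 (0.443 to 1.02) on the TMM scale, with the pericyte marker RGS5 at 17 and 15 reads against 0 and 0 in MSC. Of the 13 members, 8 had reads in HUVEC, while ACTA2, TPM2 and CSPG4 had 0 reads in both HUVEC libraries. Erythroid markers had 0 reads in each library, which by the Clopper-Pearson interval allows a share of up to 0.0163% of nuclear counts in HUVEC TiB2. This takes each read as a separate molecule, and the bound is higher otherwise.

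In every library the gene with most reads was MT-ND6, a complex I subunit and the only mitochondrial protein gene on the light strand (mitochondrial positions 14149 to 14673, minus strand). It had 14471, 13121, 2472 and 3561 reads in the order above. Among nuclear genes, LDLRAD2 had 2002 reads in HUVEC plastic and BEST1 had 1550, 942, 1469 and 2839 reads over the libraries. LDLRAD2 lies opposite HSPG2, which encodes the basement membrane proteoglycan perlecan, and BEST1 lies opposite FTH1, the ferritin heavy chain. ABI2 (opposite RAPH1), SNX22 (opposite PPIB), PPT1 (opposite CAP1), MRNIP (opposite SQSTM1) and ATP6V1C2 (opposite PDIA6) also had over 100 reads in each library. Of the nuclear genes with 50 or more reads, 73.2% in HUVEC plastic, 83.7% in HUVEC TiB2, 69.6% in MSC plastic and 70.0% in MSC TiB2 lay opposite a protein-coding exon. Among all nuclear genes this share was 13.5%, and exon length gave an expected share of 15.9% to 16.1%. Where a gene named below has such a protein-coding partner, the partner with the longest overlap is named with it.

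**Figure D1:**
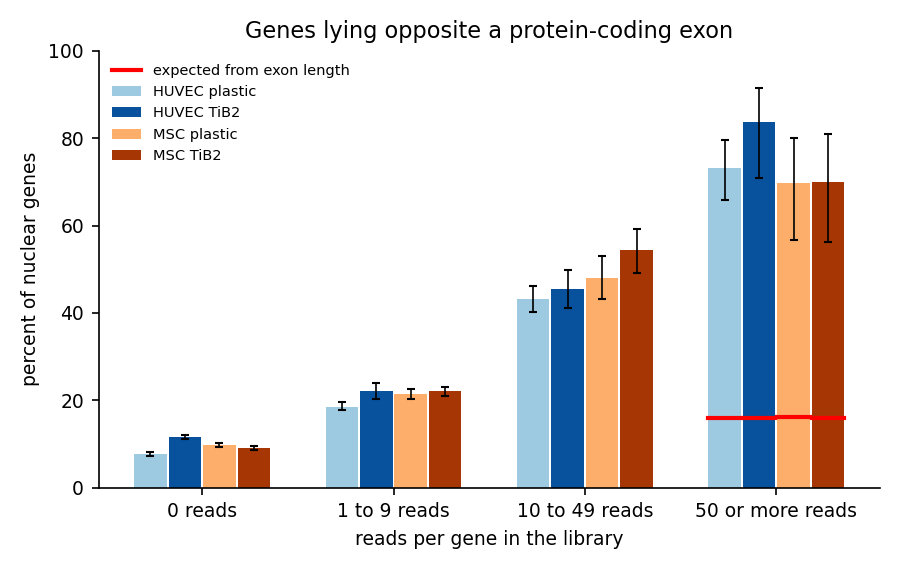
Percent of nuclear genes that lie opposite a protein-coding exon (y axis), by the number of reads per gene (x axis) in each of the 4 libraries, with Wilson 95% intervals; red lines mark the share expected from exon length. The share is 7.74% to 11.6% among genes with 0 reads and 69.6% to 83.7% among genes with 50 or more reads.

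The comparison of surfaces asked how gene expression on TiB2 differed from that on plastic, in each cell type. Mitochondrial genes took a higher share of counts in both TiB2 libraries. In HUVEC they took 23.6% on plastic (23.3 to 23.9) and 51% on TiB2 (50.6 to 51.5), a ratio of 2.17 (2.12 to 2.21). In MSC they took 10.8% (10.5 to 11.1) and 18.8% (18.4 to 19.2), a ratio of 1.74 (1.67 to 1.81). The 12 genes other than MT-ND6, which encode further subunits of respiratory complexes I, III, IV and V, differed more. Their share of all counts was 5.66% and 22.7% in HUVEC (ratio 4.0, 3.86 to 4.14) and 3.17% and 8.83% in MSC (2.78, 2.59 to 2.99), while that of MT-ND6 had ratios of 1.59 (1.55 to 1.62) and 1.30 (1.24 to 1.37). Per MT-ND6 read, the other 12 genes had 2.52 times (2.44 to 2.61) as many reads on TiB2 in HUVEC and 2.13 times (1.99 to 2.29) in MSC. In MSC this did not hold for each gene, as per nuclear read MT-ATP8 had a ratio of 0.845 (0.416 to 1.70) and MT-CO2 1.45 (1.01 to 2.08), beside 1.43 (1.36 to 1.51) for MT-ND6. The list of mitochondrially encoded genes lay at the 100th percentile of random lists in both cell types. Whether reads on these genes come from their own transcripts depends on the strand counted, which is not known.

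**Figure D2:**
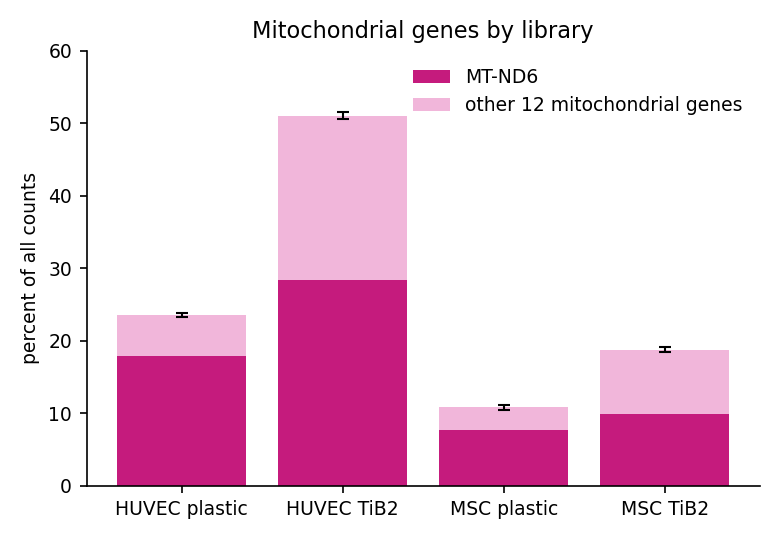
Percent of all counts (y axis) on MT-ND6 and on the other 12 mitochondrial protein genes in each of the 4 libraries; error bars are exact 95% intervals of the mitochondrial total. The total is 23.6% and 51% in HUVEC plastic and TiB2, and 10.8% and 18.8% in MSC plastic and TiB2.

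In HUVEC, among genes with a mean of at least 50 normalized reads, those highest on TiB2 relative to plastic were mitochondrial, and those lowest were nuclear genes with few or no reads on TiB2. Per nuclear read, MT-ND2 had 12.8 times as many reads on TiB2 (11.1 to 14.7) and MT-ATP8 9.97 times (7.57 to 13.3). MT-ND1 had 9.86 times (8.44 to 11.6) and MT-ATP6 8.08 times (6.98 to 9.38). On the TMM scale these were 5.67 (4.94 to 6.53), 4.42 (3.36 to 5.90), 4.38 (3.75 to 5.13) and 3.59 (3.10 to 4.16). MT-ND4, MT-ND4L, MT-CO2 and MT-CO1 followed, with ratios per nuclear read of 7.11, 6.75, 6.67 and 5.64. PRPS1L1, a paralog of the phosphoribosyl pyrophosphate synthetase PRPS1 (chromosome 7, 18026770 to 18027846), had 177 reads on plastic and 0 on TiB2. HINT3, a histidine triad nucleotide-binding protein, had 171 and 0 reads, THUMPD3, opposite SRGAP3, 154 and 0, and the circadian transcription factor CLOCK 121 and 0. If each read were a separate molecule, PRPS1L1 would be at least 21.6-fold and CLOCK at least 14.8-fold lower per nuclear read. Among nuclear genes of HUVEC TiB2 with more than 1 read, the most frequent count was 6 reads. If 6 reads stood for 1 molecule, which was not measured, the same floor would give at least 3.6-fold for PRPS1L1, 3.48-fold for HINT3, 3.13-fold for THUMPD3 and 2.46-fold for CLOCK. CPM, a carboxypeptidase gene opposite MDM2, had 251 and 3 reads, a ratio of 0.0326 (0.00669 to 0.0965). NFE2L3 had 112 and 8 reads (0.195, 0.0822 to 0.398), TSPAN31, opposite CDK4, 125 and 11 (0.240, 0.117 to 0.445), and UBE2N, opposite NUDT4, 214 and 20 (0.255, 0.153 to 0.404).

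Of the 230 HUVEC genes with at least 50 reads over both libraries, 13 were called higher and 119 lower on TiB2 on the TMM scale. On that scale the median gene stood at a log2 ratio of -1.06; relative to the median gene, 39 were higher and 50 lower. The split was 46 higher and 47 lower on the nuclear total, and 22 and 84 on total counts. HUVEC TiB2 had reads on 2428 nuclear genes, while the same number of reads drawn from HUVEC plastic covered 5486 to 5666, and 14 of the 230 genes had 0 reads on TiB2.

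**Figure D3:**
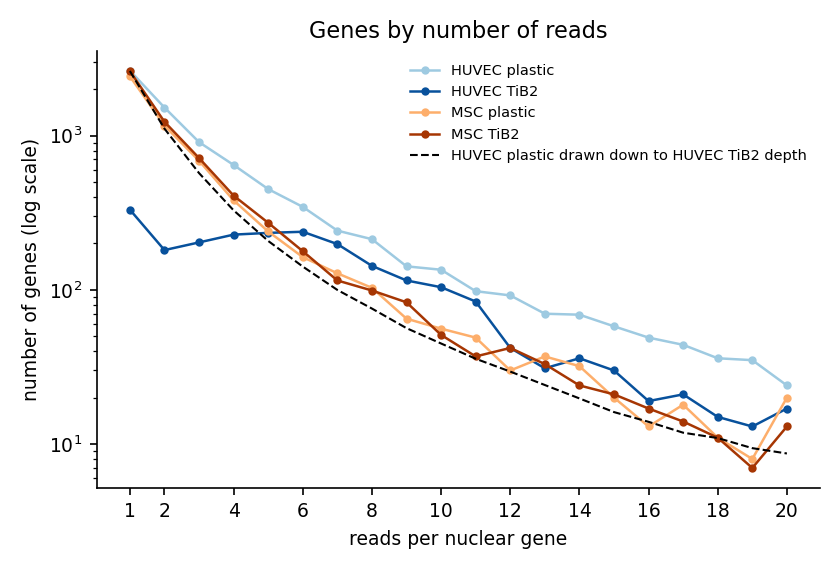
Number of nuclear genes (y axis, log scale) by reads per gene (x axis) in the 4 libraries; the dashed line is the mean of 100 draws of 22625 reads from HUVEC plastic. HUVEC TiB2 has 331 genes with 1 read and 238 with 6, against 2638 and 345 in HUVEC plastic.

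**Figure D4:**
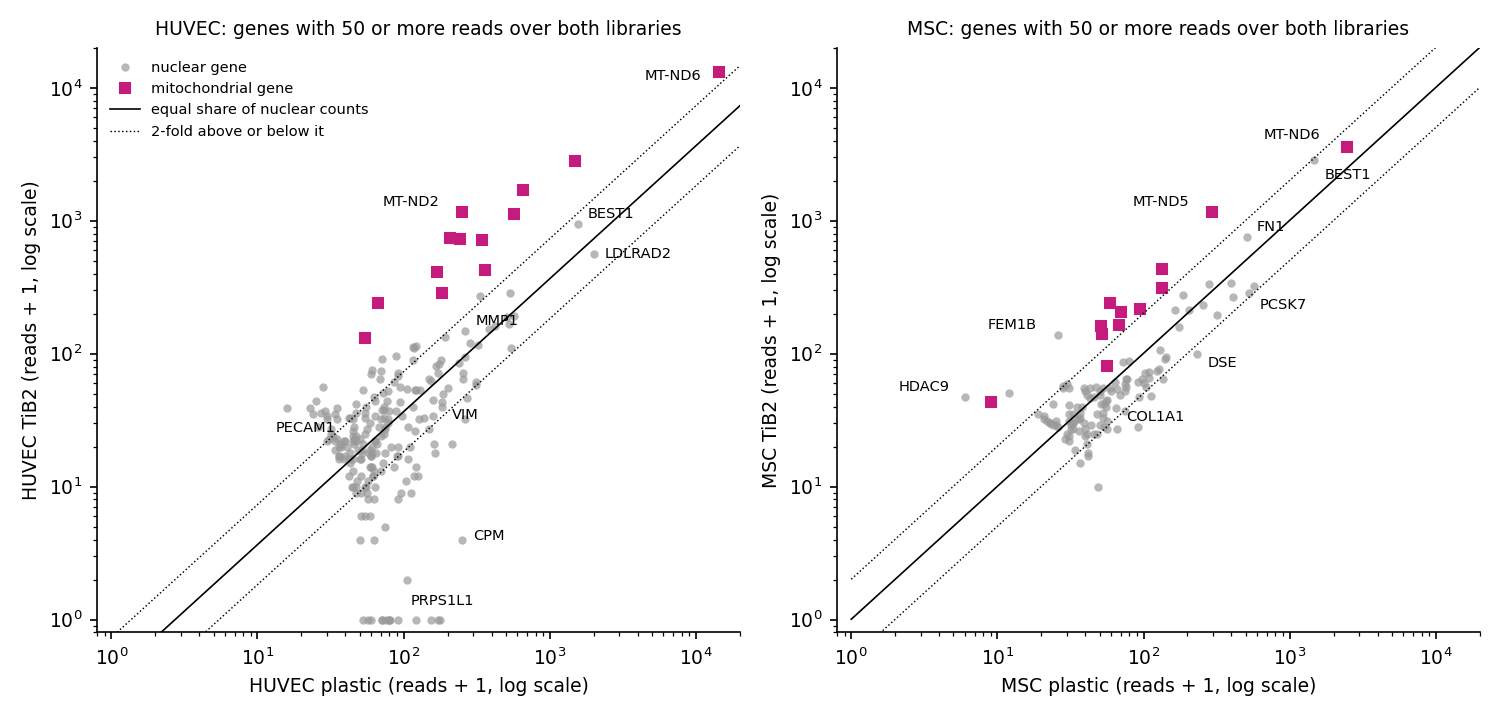
Reads per gene plus 1 on plastic (x axis, log scale) and on TiB2 (y axis, log scale) for HUVEC (230 genes) and MSC (131 genes) with 50 or more reads over both libraries. Solid lines mark an equal share of nuclear counts and dotted lines a 2-fold difference; mitochondrial genes lie above the solid line, and 14 HUVEC genes have 0 reads on TiB2.

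Among the HUVEC gene lists, ratios are pooled shares of nuclear counts, TiB2 over plastic, unless the TMM scale is named. Of the 10 lists with an interval above 1 on the nuclear scale, 8 had a ratio below 1 on the TMM scale and 0 an interval above 1, while the 9 lists with an interval below 1 had one on both scales and 15 of the 21 other lists had one on the TMM scale alone. Large ribosomal subunit proteins had a pooled ratio of 1.92 (1.69 to 2.19) over 45 members, but 0.853 (0.749 to 0.970) on the TMM scale, with RPL10 (opposite DNASE1L1) at 166 and 80 reads. The members did not move alike, as on the TMM scale 8 were at least 2-fold higher and 17 at least 2-fold lower. Among random lists they lay at the 76.8th percentile by the median and the 91.9th by the mean. Integrins had 1.54 (1.19 to 1.99), but 0.683 (0.527 to 0.882) on the TMM scale. Of them the collagen and fibronectin receptor subunit ITGB1 had 77 and 51 reads, at 1.81 (1.24 to 2.61) and on the TMM scale 0.803 (0.552 to 1.16), and the others had 1.32 (0.909 to 1.90). Nuclear genes of oxidative phosphorylation had 2.08 (1.32 to 3.23), cholesterol synthesis 2.0 (1.04 to 3.75) and ATF4 amino acid response genes 1.95 (1.18 to 3.19), but 0.921, 0.885 and 0.866 on the TMM scale. NRF2 targets had 1.48 (1.07 to 2.03) and flow-responsive endothelial genes 1.80 (1.04 to 3.05), but 0.658 and 0.797 on the TMM scale, and the latter had 1.85 (0.978 to 3.44) without NOS3 (opposite ATG9B). Metallothionein and zinc transport genes had 3.28 (1.73 to 6.25), on the TMM scale 1.45 (0.770 to 2.78), and 1.21 (0.273 to 4.35) without MT2A. Mitosis genes had 2.34 (1.39 to 3.92), on the TMM scale 1.04 (0.616 to 1.74), and 1.25 (0.645 to 2.32) without MKI67.

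Lower pooled shares on HUVEC TiB2 were found for angiogenic tip cell and Notch genes, at 0.362 (0.215 to 0.579), with ANGPT2, a TIE2 ligand, at 39 and 0 reads. Unfolded protein response genes had 0.367 (0.203 to 0.621) and p53 targets 0.273 (0.0964 to 0.630). Genes opposite the unfolded protein response members, nearly all reads of ATP6V1C2, went the other way at 2.18 (1.85 to 2.57). On the TMM scale these had 0.969 (0.823 to 1.14). Genes opposite p53 targets, mostly reads of CPM, had 0.0318 (0.00651 to 0.0938). Fibrillar collagens and their crosslinking enzymes had 0.528 (0.294 to 0.893), but 0.761 (0.417 to 1.32) without LOXL3 (opposite HTRA2), at 27 and 0 reads. Ratios were also below 1 for YAP/TAZ targets, at 0.664 (0.445 to 0.966), and basement membrane genes, at 0.700 (0.518 to 0.933), with ratios of 0.797 (0.524 to 1.18) without CRIM1 and 0.732 (0.505 to 1.04) without HSPG2. Focal adhesion genes had 0.685 (0.518 to 0.895), but 0.915 (0.675 to 1.23) without the actin crosslinker FLNA, at 90 and 7 reads. Genes of endothelial to mesenchymal transition had 0.710 (0.566 to 0.884), led by the matrix protein FN1 at 199 and 54 reads (0.741, 0.538 to 1.01, and 0.329, 0.239 to 0.446, on the TMM scale) and the intermediate filament VIM at 181 and 39 (0.588, 0.405 to 0.835). Matrix proteases and inhibitors had 1.01 (0.838 to 1.21), but 0.447 (0.372 to 0.535) on the TMM scale, made up of the collagenase MMP1 at 261 and 146 reads (1.53, 1.24 to 1.88, but 0.678, 0.550 to 0.833, on the TMM scale) and a ratio of 0.289 (0.173 to 0.459) for the others. SRF/MRTF targets had 0.988 (0.806 to 1.21), but 0.439 (0.357 to 0.535) on the TMM scale, with the actins ACTB at 97 and 33 reads (0.929, 0.606 to 1.39) and ACTG1 at 71 and 50 (1.92, 1.31 to 2.80), on the TMM scale 0.412 (0.269 to 0.618) and 0.853 (0.582 to 1.24).

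On the TMM scale, 9 of 15 angiogenic and Notch genes with reads, 10 of 13 unfolded protein response genes and 11 of 18 focal adhesion genes were at least 2-fold lower, as were 3072 of all 8754 genes with reads and 119 of the 230 with at least 50. At least 2-fold higher were 0, 1 and 4 genes of these lists, 768 of the 8754 and 13 of the 230. By the median of their members, 1 of 38 HUVEC lists lay above the central 95% of random lists, the mitochondrial one. Below it lay 2, focal adhesion at the 1.37th and unfolded protein response at the 1.90th percentile, but by the mean they lay at the 14.7th and 3.43rd. Some of 38 random lists would lie outside as well. HUVEC TiB2 had more nuclear genes at 6 reads (238) than at 2 (181). With TiB2 reads divided by 6, 1 list of 40 nuclear ones had an interval above 1 on the nuclear scale (large ribosomal proteins, 1.48 to 2.49) and 1 below (angiogenic and Notch genes, 0.0664 to 0.970).

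**Figure D5:**
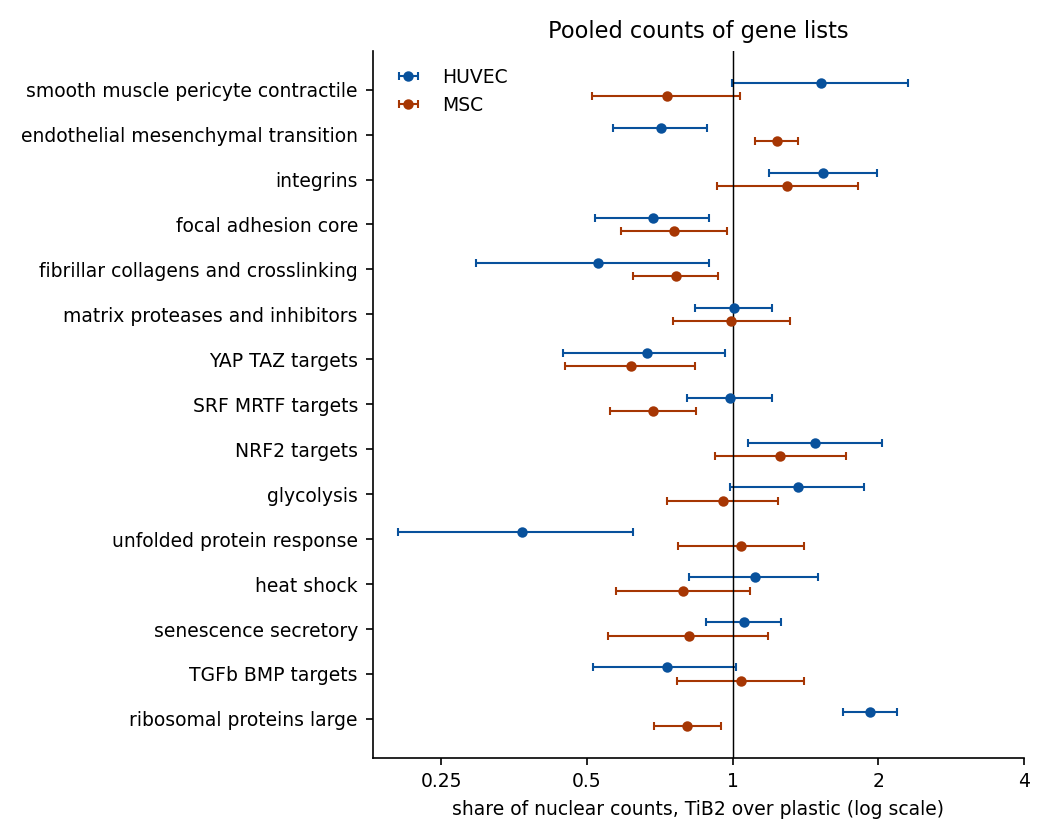
Share of nuclear counts in TiB2 over plastic (x axis, log scale) for the 15 nuclear gene lists (y axis) with at least 100 reads over both libraries in each cell type. Points are ratios of pooled counts and bars are exact 95% intervals for counting error only; large ribosomal proteins lie at 1.92 in HUVEC, but at 0.853 on the TMM scale, and at 0.806 in MSC.

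In MSC, the gene with the highest ratio among those with a mean of at least 50 normalized reads was FEM1B, a substrate receptor of a ubiquitin ligase (chromosome 15, 68277745 to 68295862), with 25 reads on plastic and 137 on TiB2. Per nuclear read it had 5.45 times as many reads on TiB2 (3.54 to 8.72). The others were mitochondrial, with ratios of 4.13 (3.09 to 5.61) for MT-CO3, 3.95 (3.47 to 4.50) for MT-ND5, 3.23 (2.65 to 3.96) for MT-ND4 and 3.18 (2.30 to 4.47) for MT-ND3, followed by MT-ND2 at 2.94, MT-ND1 at 2.71 and MT-ATP6 at 2.41. Among genes with that mean of at least 50 normalized reads, ranked by the log2 ratio with a prior count of 2, the lowest was SHLD2. This shieldin subunit gene, opposite the glutamate dehydrogenase GLUD1, had 90 and 27 reads (0.298, 0.187 to 0.463). The dermatan sulfate epimerase DSE, opposite TSPYL1, followed at 231 and 98 (0.422, 0.330 to 0.537). BAG2, an HSP70 co-chaperone opposite RAB23, had 111 and 47 reads (0.421, 0.293 to 0.597), VIM 134 and 64 (0.475, 0.347 to 0.645) and the readthrough gene P2RX5-TAX1BP3, opposite EMC6, 74 and 36 (0.484, 0.316 to 0.730).

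Of 131 MSC genes with at least 50 reads over both libraries, 14 were called higher and 11 lower on TiB2 on the TMM scale, where the median gene stood at -0.17. Relative to the median gene the split was 19 higher and 8 lower, on total counts 14 and 17, and with mitochondrial genes left out 5 and 10.

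Among the MSC gene lists, some of those of the cytoskeleton, adhesion and matrix had lower pooled shares on TiB2. SRF/MRTF targets had a ratio of 0.684 (0.557 to 0.839), YAP/TAZ targets 0.616 (0.451 to 0.838) and focal adhesion genes 0.758 (0.589 to 0.972), the last 0.751 (0.548 to 1.03) without FLNA. Fibrillar collagens and crosslinking enzymes had 0.762 (0.622 to 0.933), with COL1A1 at 64 and 38 reads (0.591, 0.385 to 0.896) and COL1A2 at 75 and 63 (0.836, 0.588 to 1.18). For smooth muscle and pericyte contractile genes, at 0.730 (0.511 to 1.04), basement membrane genes, at 0.778 (0.509 to 1.18), and matrix proteases and inhibitors, at 0.995 (0.754 to 1.31), the interval reached 1. Integrins had 1.30 (0.930 to 1.81), with ITGB1 at 45 and 46 reads and the others at 1.89 (1.09 to 3.38). Large ribosomal proteins had 0.806 (0.688 to 0.945), mitosis genes 0.497 (0.249 to 0.954), with 30 and 15 reads and 0.539 (0.252 to 1.10) without TOP2A, and immediate early genes 0.593 (0.357 to 0.966), the last 0.763 (0.423 to 1.36) without EGR1. Genes of endothelial to mesenchymal transition had 1.23 (1.11 to 1.37), which rested on FN1 at 507 and 747 reads (1.47, 1.31 to 1.64); without FN1 the ratio was 0.485 (0.364 to 0.640). Higher shares were also found for 3 lists with few reads: angiogenic and Notch genes with 7 and 28 reads (3.98, 1.70 to 10.8), of which VEGFA had 1 and 12 and the others 2.65 (0.986 to 8.28), Wnt targets with 7 and 23 (3.27, 1.36 to 9.02), of which WNT5A had 3 and 10 and the others 3.23 (0.999 to 13.6), and chondrogenic genes with 2 and 10 (4.97, 1.06 to 46.7), of which COMP had 0 and 4 and the others 2.98 (0.534 to 30.2). NRF2 targets had 1.25 (0.920 to 1.71), the unfolded protein response 1.04 (0.770 to 1.40) and glycolysis 0.954 (0.733 to 1.24). By the median of their members, 2 of 38 MSC lists lay above the central 95% of random lists and 0 lay below. They were the mitochondrial one and Wnt targets (6 members with reads) at the 98.9th percentile. Some of 38 random lists would lie outside as well. By the mean, angiogenic and Notch genes (99.6th, and 96.3rd by the median) and integrins (98.6th, and 89.5th by the median) lay above too. Focal adhesion genes (2.13th, and 16.5th by the median) and SRF/MRTF targets (2.37th, and 13.5th by the median) lay below by the mean.

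The last comparison asked whether HUVEC and MSC differed alike between surfaces. Across the 96 genes with at least 50 reads in both comparisons, the log2 ratios had a Pearson correlation of 0.469 (0.296 to 0.612) and a Spearman correlation of 0.359; genes are not independent replicates. Called higher in both were 8 genes, all mitochondrial, where independent calls would share 1.13. They were MT-ATP6, MT-CO1, MT-CYB, MT-ND1, MT-ND2, MT-ND4, MT-ND4L and MT-ND5. Called lower in both were 4 genes, where independent calls would share 1.96, among them VIM, BAG2 and MYH9, the heavy chain of non-muscle myosin. MYH9 had 104 and 1 reads in HUVEC (0.0263, 0.000659 to 0.150) and 65 and 26 in MSC (0.398, 0.242 to 0.636). Relative to the median gene 2 genes were called lower in both, MYH9 among them, while VIM stood at -0.83 in HUVEC and -0.88 in MSC and BAG2 at -0.39 in HUVEC. Lower in HUVEC and higher in MSC were SYTL4, a Rab effector of granule exocytosis opposite SRPX2, and TTN, the sarcomere protein titin, where independent calls would share 5.88; the reverse was found for 0 genes. Relative to the HUVEC median gene SYTL4 stood at -0.88, short of a call, and TTN at -1.71. Over the 84 nuclear genes among the 96 the Pearson correlation was 0.0838, and with a floor of 10 mean normalized reads (283 genes) it was 0.0636.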

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

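The pooled shares of lists below were chosen as a summary after the data were seen; the calls of single genes followed the plan. The results here had opposite directions in the 2 cell types, and the differences between the cell types were not tested, since each group had 1 library.

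SYTL4 had 71 reads on plastic and 14 on TiB2 in HUVEC, a log2 ratio of -1.93, and 8 and 42 reads in MSC, a log2 ratio of 2.13. TTN had 120 and 13 reads in HUVEC (-2.77) and 11 and 50 in MSC (1.99). SYTL4 lies opposite SRPX2 and TTN opposite the noncoding gene TTN-AS1, so these levels are uncertain. Relative to the HUVEC median gene SYTL4 stood at -0.88, which is not a call, and TTN at -1.71.

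Among the lists, large ribosomal proteins had a pooled share of nuclear counts of 1.92 times that on plastic in HUVEC and 0.806 times in MSC, but on the TMM scale both were below 1, at 0.853 and 0.807. Mitosis genes had 2.34 and 0.497, on the TMM scale 1.04 (0.616 to 1.74) and 0.498, with 35 and 30 reads in HUVEC and 30 and 15 in MSC. Without MKI67, at 0 and 14 reads, the HUVEC ratio was 1.25 (0.645 to 2.32), and without TOP2A the MSC ratio was 0.539 (0.252 to 1.10). With TiB2 reads divided by 6 the HUVEC interval was 0.716 to 6.0. Angiogenic tip cell and Notch genes had 0.362 in HUVEC and 3.98 in MSC, where they had 7 and 28 reads and a ratio of 2.65 (0.986 to 8.28) without VEGFA. Genes of endothelial to mesenchymal transition had 0.710 in HUVEC and 1.23 in MSC, the last 0.485 (0.364 to 0.640) without FN1.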

How the results depend on the processing

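Leaving out mitochondrial genes, the nuclear total, genes without an opposite exon, the pooled shares with their scalings, the scalings of the shared calls and the division by 6 were alternatives chosen after seeing the data. With 1 library per group, no tests across genes, adjusted p thresholds or leave-one-out fits were run, and no paired analysis was possible because each group had 1 library. Total counts of 32424 to 80833 limit every value, and the cause of a moved value was not tested unless the setting itself changes the genes counted.

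In HUVEC, against 13 higher and 119 lower, total counts gave 22 higher and centring on the median gene 39 higher and 50 lower. The nuclear total gave 46 and 47, and leaving out mitochondrial genes 3 higher. With no filter the counts were 768 and 3072 of 8754 genes, at a floor of 10 reads 53 and 342 of 693, at a floor of 200 reads 8 and 8 of 22, and at a log2 threshold of 2 they were 3 and 55. Genes without an opposite exon gave 10 higher and 21 lower, but of 48 genes in place of 230. Mitochondrial genes, of which 0 lie opposite a protein-coding exon, made up 10 of the 13 higher calls in HUVEC. The higher calls without an opposite exon were therefore mostly mitochondrial. In MSC, against 14 higher and 11 lower, total counts gave 17 lower, no filter 514 and 991 of 8051 genes, a floor of 10 reads 25 and 54 of 404, a floor of 200 reads 3 and 0 of 15, a log2 threshold of 0.58 gave 22 and 36, and one of 2 gave 5 and 1. Leaving out mitochondrial genes gave 5 higher, and genes without an opposite exon 11 higher and 3 lower, of 31 genes in place of 131. In MSC too these higher calls were mostly mitochondrial, as 10 of the 14 higher calls were. The other settings, among them DESeq2 size factors and prior counts of 0.1 and 5, stayed within 1.5 times. Outside these settings, edgeR's TMMwsp scaling gave 21 higher and 86 lower in HUVEC, and 14 and 11 in MSC. On it nuclear counts of HUVEC had a log2 ratio of -0.67, in place of -1.17 by TMM. Ratios of lists and named genes were not taken on that scaling, so those on the TMM scale in HUVEC depend on the scaling chosen.

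Unmatched random lists put 2 HUVEC lists above and 4 below the central 95%, against 1 and 2, and 1 MSC list above, against 2. With members at the floor only, 2 HUVEC lists lay above and 0 below, of 4 that could be placed, and 1 MSC list above, of 2. The mean in place of the median gave 1 HUVEC list below, angiogenic and Notch genes, so 0 of the 2 named lists stayed there, and 4 MSC lists above and 2 below, against 2 and 0. Of 40 nuclear lists, 10 had a higher and 9 a lower pooled share in HUVEC; without the member with most reads 5 were higher, all 5 among the 10, and 7 lower, 4 of them among the 9. With TiB2 reads divided by 6, 1 was higher and 1 lower. Against the same 10 and 9, TMM gave 0 and 27, DESeq2 size factors 0 and 28, and total counts 2 and 17; in MSC these scalings stayed within 1.5 times. In MSC 4 were higher and 7 lower; without that member 4 and 5 were, but 0 of the 4 higher lists and 4 of the 5 lower ones were the same lists.

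For the genes with 0 reads on HUVEC TiB2, division by 6 took the bound for PRPS1L1 from 21.6-fold to 3.6-fold lower. The correlation of the responses, 0.469, was 0.0636 at a floor of 10 reads, 0.894 at a floor of 200 (9 genes) and 0.0838 without mitochondrial genes. Genes called lower in both cell types numbered 4, and 19 at a threshold of 0.58, 0 at 2, and 2 both after centring and on the nuclear total. Those called higher in both numbered 8, and 0 at a threshold of 2. Those called in opposite directions numbered 2, and 4 at 0.58, 0 at 2, and 1 both after centring and on the nuclear total. Of the named genes that were called, 18 of 21 in HUVEC and 12 of 14 in MSC kept their call after centring, and none reversed under the settings run.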

Other observations

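The tests below were all chosen after the results were seen. Several of the genes with most reads lie opposite genes of the fixed lists, and the reads on them differed between surfaces. BEST1, opposite the ferritin heavy chain FTH1, had 1469 reads on MSC plastic and 2839 on MSC TiB2, 1.92 times the nuclear share (1.80 to 2.05), and FTH1 itself had 30 and 54 reads, 1.79 times (1.13 to 2.90). In HUVEC the ratio for BEST1 was 1.66 (1.53 to 1.80), but 0.736 (0.678 to 0.799) on the TMM scale. PCSK7, opposite the smooth muscle actin-binding gene TAGLN, had 528 and 287 reads in MSC (0.541, 0.467 to 0.625) and 87 and 95 in HUVEC (2.98, 2.21 to 4.04, but 1.32, 0.979 to 1.79, on the TMM scale), while TAGLN itself had 8 and 7 reads in MSC and 8 and 0 in HUVEC. LDLRAD2, opposite HSPG2, had 2002 and 562 reads in HUVEC (0.767, 0.697 to 0.842, and 0.340, 0.309 to 0.374, on the TMM scale) and 126 and 76 in MSC (0.60, 0.445 to 0.804).

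Genes opposite members of a list, pooled, gave 1.87 (1.76 to 1.98) for NRF2 targets in MSC and 1.47 (1.36 to 1.58) in HUVEC, the last 0.650 (0.604 to 0.699) on the TMM scale. These were mostly reads of BEST1. Those opposite SRF/MRTF targets were nearly all reads of PCSK7. Those opposite basement membrane genes gave 0.786 (0.721 to 0.857) in HUVEC, on the TMM scale 0.349 (0.320 to 0.380), and 0.726 (0.561 to 0.937) in MSC, mostly reads of LDLRAD2. Those opposite unfolded protein response genes, nearly all on ATP6V1C2 opposite PDIA6, gave 2.18 (1.85 to 2.57) in HUVEC, on the TMM scale 0.969 (0.823 to 1.14), where the members themselves gave 0.367 and 0.163. PRR29, opposite the endothelial adhesion gene ICAM2, had 240 and 84 reads in HUVEC and 3 and 0 in MSC.

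In all 4 libraries reads gathered on MT-ND6 and on genes opposite other genes. Exon length does not account for this, with an expected share of at most 16.1% against 69.6% or more observed, and counting without regard to strand would give the partner about as many reads as the gene, while the median partner had at most 9.31%. A candidate explanation is that reads of this stranded kit were counted on the strand opposite to the transcripts, so that reads on BEST1 would come from FTH1. Values given above for a gene with such a partner would then mostly describe transcripts of the partner. The endothelial and stromal marker lists had 0 members opposite a protein-coding exon, and their reads still followed the cell type labels. Endothelial markers had 173 reads in HUVEC plastic and 1 in MSC plastic, and stromal markers 35 and 209. What reads on genes without a partner would describe was not tested. The counts were also only 1.52% to 8.12% of the reads implied by the RPKM values, though what those include is not given. The MSC over HUVEC ratios of genes on plastic followed those of their partners over 155 pairs (Pearson 0.300, Spearman 0.280, one-sided permutation p = 0.0003 over 10000 shuffles of the pairs). Pairs entered only where the gene had more reads than its partner. Some reads from the wrong strand under correct counting, or neighbouring genes that vary alike, would also give a positive correlation. The correlation therefore cannot decide between these. Pairs are not independent replicates, the strand setting is not given in the sources used here, and no biological explanation was tested.

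HUVEC TiB2 had reads on few genes for its depth. Lower depth alone is argued against, since as many reads drawn from HUVEC plastic left at least 5486 nuclear genes in 100 draws, against 2428. There were 0.719 genes with 6 reads per gene with 1 read, against at most 0.0657 in the draws and 0.131, 0.0673 and 0.0681 in the other libraries. This is consistent with few starting molecules that were each read several times, in which case the intervals given for this library are too narrow. Whether HUVEC expressed fewer genes on TiB2 stays open, as untested.

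On TiB2 the other 12 mitochondrial genes, pooled, gained more reads than MT-ND6 in both cell types, with MT-ATP8 (0.845 per nuclear read) and MT-CO2 (1.45, beside 1.43 for MT-ND6) as exceptions in MSC. More reads from the wrong strand on TiB2 would raise the partner reads per gene read of opposite pairs alike, but over 6 pairs with at least 100 reads in each library this ratio was 0.902 times that on plastic in HUVEC (0.557 to 1.43 on all reads and, in a later and stricter step, 0.303 to 2.37 with TiB2 reads divided by 6, against a gain of at least 2.39) and 1.13 times in MSC (0.798 to 1.61, against at least 1.99), a margin that in HUVEC is thin and rests on 28 reads. Mitochondrial DNA as the whole cause would add about equal reads per kilobase, but the highest and lowest of the genes of 500 bases or more differed 3.36-fold in HUVEC (MT-ND5 over MT-CO3) and 13.3-fold in MSC (MT-ND5 over MT-CO2), provided that DNA is read evenly. Part of the gain may still come from DNA, and olfactory receptor genes, which these cells are not known to express, had 53, 27, 12 and 20 reads, too few to decide. A difference in mitochondrial RNA between surfaces stays open as a hypothesis, and its strand depends on the counting weighed above.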
